A study of Mus musculus with 6 samples.

How the data were processed

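Single-cell RNA was measured in 6 libraries from C57BL/6 mice. Per the labels' protocols, 5 of them came from haematopoietic stem cells (HSCs) sorted as CD150+ CD34-/lo c-Kit+ Sca1+ Lineage- and grown for 4 weeks in Ham's F12 medium with 1 mg/ml polyvinyl alcohol, 100 ng/ml thrombopoietin and 10 ng/ml stem cell factor, at 37 C and 10% carbon dioxide on plates coated with fibronectin. The oxygen level was 20% (1 library), 5% (2 libraries) or 1% (2 libraries), and the remaining library was uncultured c-Kit+ bone marrow. The libraries were prepared with a 10x Genomics gene expression kit, per the labels' protocols. Reads were processed with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. The deposited matrices hold a raw UMI count per gene and barcode, which the authors left unnormalised: all values were whole numbers, over 31053 features given as Ensembl identifiers with symbols. Neither the version of the kit nor the gene annotation is stated. Coordinates were looked up by Ensembl identifier in GENCODE M21 (GRCm38), where all 645 of the 645 genes looked up were found.

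A barcode was kept with at least 500 detected genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, unless Scrublet called it a doublet. Scrublet was run per library through scanpy 1.11.5 with an expected rate of 0.8% per 1000 barcodes and its automatic threshold. It called 563 cells (6.03%) in the second 1% oxygen library, but 0 in the fresh library, 9 (0.157%) in the 20% library, 0 and 11 (0.370%) in the 5% libraries and 7 (0.389%) in the first 1% library. The automatic threshold thus failed in 5 of the 6 libraries, where few or no doublets were removed, and in the 1% against 5% comparison almost all the removed cells came from 1 library of 1 side. In all, 31758 cells were kept. Counts were scaled to 10000 per cell and logged, and the 2000 most variable genes were reduced to 30 principal components. Cells were then clustered with 15 neighbours by the Leiden method at resolution 1.0 (leidenalg 0.10.2), the 5 cultured libraries together and the fresh library alone, without integration. Genes of the hypoxia response, glycolysis, S phase, G2 and M phase and sex-linked lists and the mitochondrial genes took no part in the clustering. A cluster was called by a cell type, as "HSC-like", only from 12 marker lists. The scoring rule was set after the data had been seen. It asked for at least 3 raised markers (a log2 rise of 0.25 in 10.0% of the cluster's cells), a mean marker score of 0.5 and a gap of 0.2 to the next class. It also asked for no greater number of another class's markers among the cluster's 10 leading genes.

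For tests, counts were summed over all kept cells of a library, since cells are not replicates, and again over its HSC-like cells. The 5 cultured libraries were fitted together with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood fit, 2 residual degrees of freedom) and the 3 oxygen contrasts were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The filter left 15222 genes in whole libraries and 13716 in HSC-like cells. The biological coefficient of variation was 0.0888. The 20% oxygen level has a single library, which is assumed to vary like the 5% and 1% libraries. Standard errors (SE) were approximated from the fold change and its F statistic. Gene lists (12 marker lists and 16 lists of functions) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 28 lists. The lists of functions are hypoxia response, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, antioxidant response, p53 targets, cholesterol synthesis, integrated stress response, unfolded protein response, interferon response, immediate early genes, cytokine STAT5 targets, S phase, G2 and M phase, a sex-linked check of pooled animals, and ribosomal proteins. The ribosomal list takes every symbol starting Rps or Rpl and a digit, so it also holds Rps6k kinases and pseudogenes. Fresh marrow has 1 library and was compared by CPM (counts scaled to the same library total) without a test. Shares of cells with a UMI of a marker gene were compared after each cell was thinned to 2000 UMIs, with 95% exact (Clopper-Pearson) binomial intervals.

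The genes named in the text follow a rule. For each oxygen contrast these are the 10 largest rises and 10 largest falls past the threshold with a mean CPM of at least 20 in the higher group, and without overlap between libraries where both groups have 2. Gene models named Gm or ending in Rik and ribosomal proteins are passed over. Up to 5 members each of the hypoxia, glycolysis and HSC-like lists with the smallest p are added. For HSC-like cells the rule takes 5 each way, for the difference between cell classes the 5 smallest adjusted p, and for fresh marrow the 10 largest CPM ratios each way among genes of at least 100 CPM in the higher side. Members of the other lists are examples by smallest p, and not every gene the rule takes is named in the text. The design, marker lists, gene lists, naming rule for genes and most alternatives were fixed before the data were examined.

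The test was tried on simulated counts drawn from the real means and library sizes with 200 changed genes per comparison. All libraries, the 20% one included, were drawn from the same means, with a spread set only by the mean level of a gene. The rates below therefore take for granted that the 20% library varies like the others. They do not cover contrasts in which far more genes change. For 1% against 5% oxygen (14861 genes) it recovered 49.2% of 1.5-fold, 78.3% of 2-fold and 90.6% of 4-fold changes, and 9.49% of its calls were unchanged genes. For 20% against 5% (14862 genes) it recovered 55.8%, 71.2% and 94.3% of these fold sizes, with 8.70% unchanged genes among its calls. For 20% against 1% (14884 genes) it recovered 47.9%, 62.5% and 88.7%, with 0.769% unchanged genes among its calls. The alternatives were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, leaving out each 5% and 1% library, all deposited barcodes, a stricter cell filter (2000 genes, 5% mitochondrial UMIs), called doublets kept, cells thinned to 2000 UMIs, the replicate number as a block, only the 4 libraries at 5% and 1% oxygen, equal cluster shares, other clustering settings, other depths and other CPM floors. Alternatives added after the data had been seen were removal of the highest doublet scores at the same rate everywhere, removal of the 6 clusters whose best-scoring class was neutrophil-like, mast or basophil-like or megakaryocyte-like, and removal of a cluster led by interferon genes. One more test, also chosen then, used the cells in which neutrophil, mast or basophil, eosinophil and megakaryocyte markers together made up no more of the UMIs than in the median cell at 5% oxygen (6.44 per 10000), with and without cluster 4. Of the 6 clusters 4 were unnamed, among them cluster 8, led by histone genes. For the HSC-like fit the stricter filter was applied to the HSC-like cells of the original clustering. For class shares under any alternative clustering or cell set, and for the HSC-like fit with doublets kept, the cells were clustered and named again. The planned test of whether the oxygen effect differs between HSC-like cells and the largest other named class could not be made, since no other named class had 50 cells in every cultured library, and all other kept cells took its place. Equal shares were given to clusters and not to named classes, since many cells were in unnamed clusters. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.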

Results

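The libraries fell into 4 groups: fresh c-Kit+ bone marrow (1 library) and HSC cultures harvested at day 28 after growth in 20% oxygen (1 library), 5% oxygen (2 libraries) or 1% oxygen (2 libraries). Polyvinyl alcohol replaces serum albumin in such cultures, and oxygen was the variable that differed between them. The deposited files held 14117 barcodes for fresh marrow, 6076 at 20% oxygen, 3789 and 4554 at 5% oxygen, and 2652 and 10610 at 1% oxygen. Total UMI counts, in the same order, were 128885052, 154314022, 55671395, 89706533, 30488416 and 71128380. After filtering, 10160 fresh cells, 5710 cells at 20%, 2358 and 2962 at 5%, and 1791 and 8777 at 1% oxygen were kept. The median UMIs per kept cell were 6320 in fresh marrow, 25278 at 20%, 19075 and 24981 at 5%, and 14402 and 6622 at 1% oxygen, so cells of the second 1% library were shallower than those of the other cultures. The labels do not say whether replicates came from separate cultures, and the p-values measure only the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

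The first comparison asked how cultures at 1% oxygen differed from those at 5%, the only pair of levels with 2 libraries each. At 1% oxygen, genes of the hypoxia response were higher. Slc2a1, the glucose transporter GLUT1, rose 2.67-fold (log2 fold change 1.42 ± 0.09 SE, adjusted p = 1.14e-06), from 17.5 and 17.2 CPM to 50.9 and 43.5 CPM. Egln3, a prolyl hydroxylase that marks HIF for degradation, rose 2.51-fold (1.33 ± 0.09, adjusted p = 1.95e-06). Genes of cholesterol synthesis also rose, led by Hmgcs1, the HMG-CoA synthase, at 2.09-fold (1.06 ± 0.09, adjusted p = 1.09e-05). Interferon-induced genes fell, with Ifi44 at -1.39 ± 0.09 on the log2 scale (adjusted p = 1.14e-06) and CPM of 69.5 and 71.2 at 5% against 26.4 and 28.1 at 1% oxygen. Slc2a1 (ENSMUSG00000028645) lies on chromosome 4 at 119108711 to 119137983 of GRCm38, Egln3 (ENSMUSG00000035105) on chromosome 12 at 54178981 to 54203860, Hmgcs1 (ENSMUSG00000093930) on chromosome 13 at 119690379 to 119708260, and Ifi44 (ENSMUSG00000028037) on chromosome 3 at 151730922 to 151749960. All 4 are protein-coding genes.

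Other large rises at 1% oxygen included the log2 changes of Ero1l (1.15), an endoplasmic reticulum oxidase, Slc16a3 (1.14), a lactate exporter, Il10ra (1.08), the interleukin-10 receptor, and the histone gene Hist3h2ba (1.22). Bnip3, a mitophagy receptor, rose by 1.53 (adjusted p = 0.0423) and Plod2, a collagen-modifying hydroxylase, by 1.17 (adjusted p = 0.0336). Both calls ended when either 1% library was left out. Such a fit has fewer residual degrees of freedom and takes a gene's spread from the replicated group that remains. A call lost in this way, here and below, therefore does not show that the library left out drove the change. The 1% libraries were close for Bnip3, at 283 and 299 CPM, against 121 and 79.5 at 5% oxygen. Plac8, a gene of early lymphoid and myeloid progenitors, had the second largest fall at -1.76 ± 0.12 (adjusted p = 1.85e-05), from 193 and 236 CPM to 61.3 and 67.1 CPM. Lgals3 fell by 1.30, Oas1a by 1.34, Ccl6 by 1.27, Slfn5 by 1.21 and Iigp1 by 1.12. The lysosomal protease gene Ctss (-1.77, adjusted p = 0.0345), lysozyme gene Lyz2 (-1.44, adjusted p = 0.0437) and MHC class II gene H2-Aa (-1.63, adjusted p = 0.00953) also fell. The calls of Ctss and Lyz2 ended without the first 5% library and that of H2-Aa without the second 1% library, with the same limit.

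**Figure D1:**
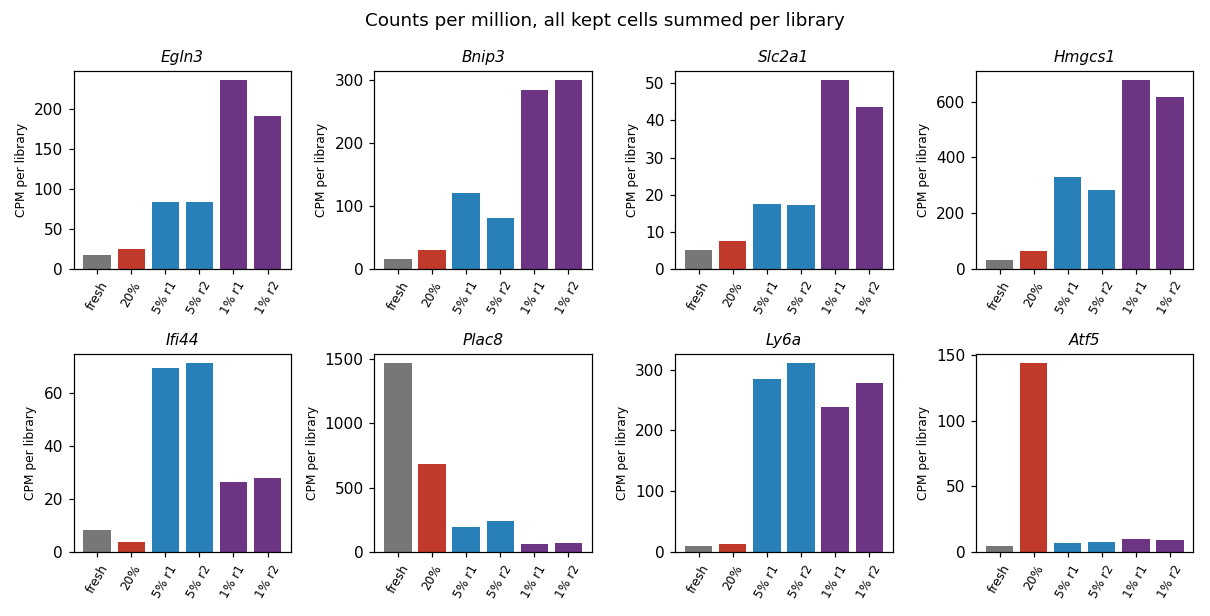
CPM (vertical axes, from 0) of 8 genes in each of the 6 libraries, with all kept cells of a library summed; each bar is 1 library. Egln3 was at 235 and 191 CPM at 1% oxygen against 82.9 and 83.8 at 5% and 24.5 at 20%, whereas Atf5 was at 144 CPM at 20% oxygen and between 7.14 and 10.1 in the other cultures.

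Over all genes tested, edgeR's quasi-likelihood test called 444 genes higher and 439 lower at 1% than at 5% oxygen. Of the hypoxia response list, 26 of 37 tested members rose and 0 fell, among them Fam162a (0.79), and 26 rose and 1 fell when adjusted over the list alone (median log2 fold 0.67). Of 18 glycolysis genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with rises of Pfkp (1.00), Tpi1 (0.68), Pgam1 (0.65), Pkm (0.63) and Pfkl (0.52) and a fall of Hk3 (-0.91). Of 24 cholesterol synthesis genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone), with Lss at 1.04 and Mvd at 1.00. Of 23 interferon response genes, 17 fell and 0 rose (20 and 0 adjusted over the list alone), with Oasl2 at -0.86 and Ifit1 at -0.84. These 4 lists passed camera at its preset correlation, with adjusted p of 5.42e-16, 8.49e-08, 4.41e-17 and 3.12e-12, and lost the call at adjusted p = 0.451 with an estimated correlation. The test fry, which asks only whether a list moves one way and makes no comparison with other genes, gave adjusted p of 0.0403, 0.00769, 0.0358 and 0.0557. No list in any contrast kept its camera call with an estimated correlation.

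Genes of G2 and M phase were also higher at 1% oxygen: 22 of 51 rose and 0 fell (40 and 0 adjusted over the list alone), including Hjurp (0.68), Mki67 (0.57) and Cdc20 (0.56). The list's adjusted p was 6.81e-15 by camera at the preset correlation, 0.524 with an estimated correlation and 0.162 by fry. Of 42 S phase genes only Cdc45 rose (0.37) and only Pcna fell (-0.31). Of 13 monocyte or dendritic markers, 6 fell and 0 rose (7 and 0 adjusted over the list alone), with Klf4 at -1.03 and Ly86 at -1.14. That list's adjusted p was 3.03e-07 by camera at the preset correlation, 0.524 with an estimated correlation and 0.134 by fry. Of 18 HSC-like markers, 4 fell and 0 rose (6 and 0 adjusted over the list alone). Ctnnal1 was at -0.91, Mllt3, a regulator of HSC maintenance, at -0.57, Pdzk1ip1 at -0.55 and Esam at -0.83. Tcf15, which marks quiescent HSCs, had a log2 fold of -0.68 and did not pass (adjusted p = 0.0990), though without the first 1% library it did (0.0118). The calls of Pdzk1ip1 and Esam ended without the first 5% library (adjusted p = 0.173 and 0.289) and without the second 1% library (0.163 and 0.248). The HSC-like list had an adjusted p of 0.00152 by camera at the preset correlation, 0.524 with an estimated correlation and 0.228 by fry. Of 10 multipotent or lymphoid-primed progenitor markers, 4 fell and 0 rose, among them Il7r (-0.87), Dntt (-1.11) and Cd48 (-0.46). Of 13 mitochondrially encoded genes, 3 fell and 0 rose, with mt-Cytb at -0.76 and mt-Nd4 at -0.70. That list's adjusted p was 0.00559 by camera at the preset correlation, 0.524 with an estimated correlation and 0.202 by fry. The cell filter acts on these same counts. Barcodes over its limit of 10% mitochondrial UMIs made up 35.4% and 32.9% at 5% oxygen and 30.2% and 11.7% at 1% oxygen.

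In the remaining lists few members changed between 1% and 5% oxygen. The integrated stress response list had 5 rises, led by Vldlr (0.88), and 1 fall, Slc7a5 (-0.48), among 23. The erythroid markers Hbb-bt (-0.48) and Car1, which had 0 counts in both 1% libraries, and the lymphoid genes Nkg7 (-0.39) and Klrd1 (-0.49) of the T or NK list fell. The macrophage list had 1 rise, C1qb, which rested on 2 counts at 5% oxygen, and 2 falls, Ctsb (-0.41) and Adgre1 (-0.92), and its median was -0.40 while its mean was 0.72. The megakaryocyte list had 2 rises, Itgb3 and Pf4, and 0 falls, with a median of 0.03 and a mean of -0.05. The STAT5 target list had a rise of Cd69 (0.67) and a fall of Socs2 (-0.44), with a median of 0.01 and a mean of -0.01. The p53 list had 1 rise, nuclear oxidative phosphorylation 1 rise and 1 fall, immediate early genes 1 fall, and ribosomal proteins 1 rise and 5 falls among 96. Over the 28 lists of this contrast the adjusted p with an estimated correlation lay between 0.451 and 0.975. None of the mast or basophil, eosinophil, neutrophil, B-lymphoid, stromal or endothelial, antioxidant, unfolded protein and sex-linked lists had a member past the threshold by edgeR over all genes; adjusted over the list alone, 4 mast or basophil genes and 2 stromal or endothelial genes fell.

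The call count depended on the cells and libraries used. It was 573 without the first 5% library, 553 with the stricter cell filter and 580 with cells thinned to 2000 UMIs, against 883 in all. With each library given the same share of each of 12 clusters, which held 96.6% of the cells, the medians of the hypoxia (0.73), glycolysis (0.42) and cholesterol (0.55) lists were close to the values above, while those of the interferon (-0.23), monocyte or dendritic (-0.09), HSC-like (-0.03), progenitor (-0.03), erythroid (-0.05) and G2 and M phase (0.14) lists were nearer 0. Over the 883 called genes, 827 kept their direction with equal shares, with a Pearson correlation of 0.695 and a slope of 0.337, so the values as a whole were smaller. Equal-share values are ratios of averaged cluster CPM with a pseudocount of 0.5 CPM and not edgeR folds. The pseudocount alone brings genes of few counts nearer 0, so the slope and such medians do not measure cluster shares alone. Bnip3 (1.55), Slc2a1 (1.45), Egln3 (1.30), Hmgcs1 (1.03), Il10ra (1.07) and Plac8 (-1.58) stayed close to their values above, whereas Ifi44 was at -0.67, Slfn5 at -0.38, Iigp1 at -0.33, H2-Aa at -0.46 and Mllt3 at -0.11. Lgals3 (0.54), Ccl6 (0.46), Lyz2 (0.37), Ctss (0.13) and Pdzk1ip1 (0.03) no longer fell. Clusters with fewer than 10 cells in any of the 5% and 1% libraries took no part, among them the neutrophil-like cluster 12 and cluster 15. The falls of these genes in whole libraries thus depended on the cluster shares or on the cells left out. These equal-share values have no test.

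The 20% oxygen culture differed from the 5% cultures in its cell types and in stress genes. Atf5, a transcription factor of the integrated stress response, was 22.8-fold higher at 20% oxygen (log2 fold 4.51 ± 0.11, adjusted p = 8.42e-13), at 144 CPM against 7.14 and 7.29. Mast cell and basophil genes were higher, including Cpa3, the mast cell carboxypeptidase (3.98 ± 0.20, adjusted p = 4.67e-05). Fcer1a, a chain of the IgE receptor, was at 87.0 CPM from 13260 counts against 1 count in both 5% libraries, a ratio of 10882 with a counting interval of 1953 to 429847. Ly6a, which encodes the stem cell antigen Sca-1, was lower at 20% oxygen (-4.25 ± 0.16, adjusted p = 8.50e-10), at 13.6 CPM against 285 and 310. Atf5 (ENSMUSG00000038539) lies on chromosome 7 at 44812256 to 44816658, Cpa3 (ENSMUSG00000001865) on chromosome 3 at 20215620 to 20242181, Fcer1a (ENSMUSG00000005339) on chromosome 1 at 173221284 to 173227214 and Ly6a (ENSMUSG00000075602) on chromosome 15 at 74994877 to 74998031. The single 20% library was taken to vary like the others, so these calls have no replicate check of their own. Most of its cells also lay in clusters nearly absent from the other cultures. In both contrasts with 20% oxygen the oxygen level therefore cannot be told apart from the cell types or from that library.

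Other large rises at 20% against 5% oxygen were Fgf3 (5.93), Serpinb2 (5.40), the muscle LIM protein gene Csrp3 (4.85) and Cox6a2 (3.82), and the eosinophil granule gene Prg2, with a ratio of 1330 (counting interval 368 to 10989) from 3242 against 2 counts. S100a9, a neutrophil calgranulin (9.36, adjusted p = 0.0138), and Ms4a2, an IgE receptor chain (4.60, adjusted p = 0.00536), also rose. Both calls ended when either 1% library was left out. Those libraries are not part of this contrast and enter it mainly through the estimate of the spread. The largest falls included the interferon-induced genes Ifi27l2a (-4.99), Iigp1 (-4.65), Ifi44 (-4.08), Ifit1 (-3.56) and Oas3 (-3.44), the lipid gene Scd1 (-4.50), a fatty acid desaturase, and Gimap4 (-4.43) and the globin gene Hbb-bt (-3.80).

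By edgeR's quasi-likelihood test 2600 genes were higher and 2455 lower at 20% than at 5% oxygen. All 23 tested members of the integrated stress response list rose, both over all genes and adjusted over the list alone, with a median log2 fold of 1.09. They included Nupr1 (3.38), Trib3 (2.92), Ddit3 (2.87), which encodes CHOP, and Asns (2.00), the asparagine synthetase. Of 21 p53 targets, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Cdkn1a at 1.48, Sesn2 at 1.62 and Bbc3 at 1.81. Cholesterol synthesis genes were lower, with 23 falls and 0 rises among 24 (median -1.62, the same counts adjusted over the list alone), and so were interferon response genes, with 22 falls and 0 rises among 23 (median -1.69, likewise). Of 18 glycolysis genes, 10 fell, among them Aldoc (-2.42), Tpi1 (-1.75), Eno1 (-1.73) and Pgk1 (-1.58), and Hk3 rose (2.23); adjusted over the list alone the counts were 13 and 1. These 5 lists passed camera at the preset correlation and had an adjusted p = 0.344 with an estimated correlation. Of 37 hypoxia response genes, 16 fell, including Slc16a3 (-2.52), Egln3 (-1.57), Ak4 (-1.42), Anxa2 (-1.29) and Prelid2 (-1.20), and 4 rose (the same adjusted over the list alone). That list's adjusted p was 0.00475 by camera at the preset correlation and 0.555 with an estimated correlation.

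Marker lists moved in opposite directions. Of 10 mast or basophil genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, median 4.39), of 12 megakaryocyte genes 10 rose and 1 fell (11 and 1, median 2.27; Gp5 4.21, Itga2b 2.04), and of 15 neutrophil genes 7 rose and 0 fell (9 and 0, median 2.76; Cebpe 4.35, Ctsg 2.76). In this order their adjusted p was 3.86e-08, 5.86e-06 and 2.63e-05 by camera at the preset correlation. Each had an adjusted p = 0.344 with an estimated correlation. Of 18 HSC-like markers, 8 fell and 1 rose (11 and 1 adjusted over the list alone), with Mllt3 at -1.29, Mmrn1 at -1.29, Mecom at -1.84 and Ctnnal1 at -0.94. That list's adjusted p was 0.00191 by camera at the preset correlation and 0.555 with an estimated correlation. The one rise, Trpc6 (4.10), lost its call when all clusters with neutrophil, mast or basophil, or megakaryocyte markers as their best-scoring class were left out, unnamed ones included (1.53, adjusted p = 0.0652), a setting chosen after the data had been seen. G2 and M phase genes had 33 falls and 1 rise among 51 and S phase genes 16 falls and 2 rises among 42. Their adjusted p was 3.07e-07 and 0.00266 by camera at the preset correlation, and 0.566 and 0.650 with an estimated correlation. In the cells poor in lineage markers, a set chosen after the data had been seen, the G2 and M phase median was -0.73. With cluster 4 taken out of that set it was 0.30, so the direction depended on the cells used. The S phase medians were -0.40 and -0.22. STAT5 targets had 5 falls and 0 rises among 10, with Pim2 at -1.85 and Socs2 at -1.48, and ribosomal proteins 57 rises and 2 falls among 96. Over the 28 lists the adjusted p with an estimated correlation lay between 0.344 and 0.956. With cells thinned to 2000 UMIs the call count for this contrast was 2928.

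The third contrast set 20% against 1% oxygen, with the same limits of a single 20% library and its other cell types. Egln3 was lower at 20% oxygen (-2.90 ± 0.13, adjusted p = 7.38e-10), and so were Slc2a1 (-2.44), Ak4 (-2.37) and Fam162a (-1.70), so that 22 of 37 hypoxia response genes fell and 2 rose (25 and 2 adjusted over the list alone, median -1.03). The lactate exporter Slc16a3 (-3.66), the lipid genes Scd1 (-5.27) and Lss (-3.19), and Gimap4 (-4.53), Ly6a (-4.03), Ifi27l2a (-3.89), Itsn1 (-3.68), Ccl5 (-3.55) and Hbb-bt (-3.33) were among the 10 largest falls. Fcer1a had 0 counts in both 1% libraries and was at least 2573-fold higher at 20% oxygen, on a floor of 3 counts over the 1% group. Prg2 (8.46), Fgf3 (6.65), Csrp3 (6.25), Serpinb2 (6.04), Gda (5.11), Cpa3 (4.45) and Atf5 (4.15) rose. S100a9 (11.07, adjusted p = 0.0131) and Ms4a2 (7.94, adjusted p = 0.00264) rose too, but neither call held without the first or without the second 1% library.

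In all 2973 genes were higher and 2840 lower at 20% than at 1% oxygen by edgeR's quasi-likelihood test (3732 in all with cells thinned to 2000 UMIs). Of 18 glycolysis genes 13 fell and 1 rose (the same adjusted over the list alone), with Aldoc at -2.71, Tpi1 at -2.43, Eno1 at -1.96, Pgk1 at -1.98 and Pfkl at -1.74. Of 24 cholesterol synthesis genes 23 fell and 0 rose (the same adjusted over the list alone, median -2.22), of 23 interferon genes 19 fell and 0 rose (21 and 0), and of 51 G2 and M phase genes 45 fell and 1 rose (46 and 1). Among the cells poor in lineage markers the G2 and M phase median was -1.08, and -0.02 with cluster 4 taken out. The integrated stress response list had 19 rises and 0 falls (20 and 0 adjusted over the list alone). The glycolysis, stress, hypoxia, cholesterol, interferon and G2 and M phase lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.340 for the glycolysis and stress lists, 0.405 for the hypoxia, cholesterol and interferon lists and 0.518 for G2 and M phase. Mast or basophil genes had 8 rises and 0 falls (median 5.84, or 5.74 with genes at 0 in a group set to their bound), and monocyte or dendritic genes 7 rises and 1 fall. Their adjusted p was 6.60e-08 and 0.000207 by camera at the preset correlation, and 0.405 and 0.518 with an estimated correlation. Of the 18 HSC-like markers 4 rose and 6 fell, the falls including Mmrn1 (-1.24), Mllt3 (-0.72) and Mecom (-1.57). The rises included Trpc6 (3.51), at 1.94 CPM at 20% oxygen. The list did not pass camera at the preset correlation (adjusted p = 0.135).

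**Figure D2:**
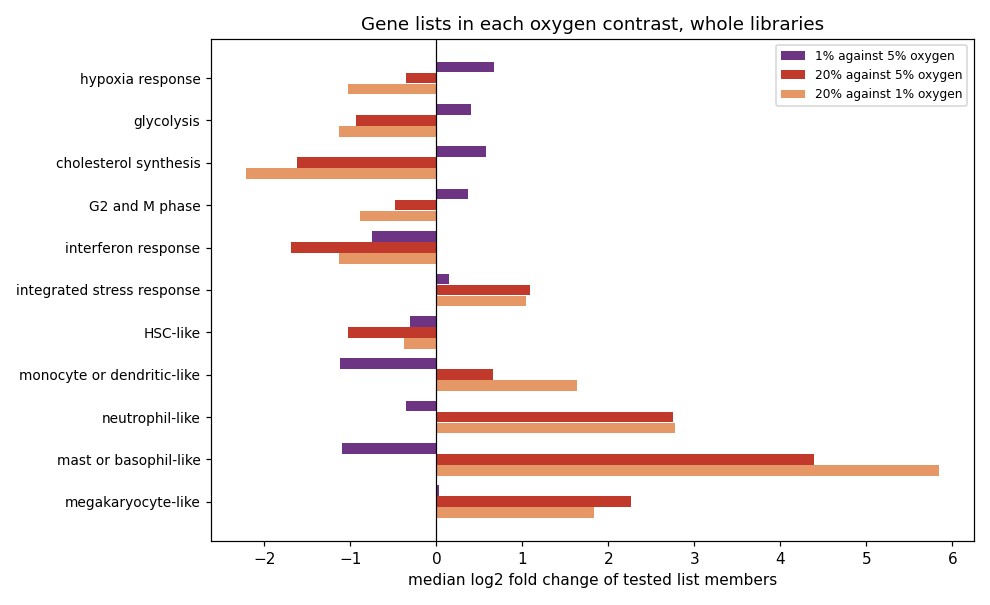
Median log2 fold change (horizontal axis) of the tested members of 11 gene lists in the 3 oxygen contrasts on whole libraries; each bar is 1 list in 1 contrast. The hypoxia response median was 0.67 for 1% against 5% oxygen, -0.36 for 20% against 5% and -1.03 for 20% against 1%. Both contrasts with 20% oxygen rest on 1 library, whose cells were mostly in clusters nearly absent from the other cultures.

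Clustering asked which cell types the cultures held. HSC-like cells made up 64.1% and 63.6% of kept cells at 5% oxygen, 56.8% and 47.2% at 1% oxygen and 0.298% (17 cells) at 20% oxygen. At 5% oxygen cluster 3 held the largest part of them (28.9% and 30.3% of kept cells), with the rest in clusters 1, 2 and 9, and at 1% oxygen most were in clusters 1 (23.8% and 24.2%) and 2 (15.1% and 17.5%). Cluster 2 was led by mitotic genes such as Ube2c and Cenpf, and cluster 9, also HSC-like, by the interferon genes Ifit1, Iigp1 and Ifi44. Cluster 9 held 10.5% and 11.8% of cells at 5% and 6.09% and 1.67% at 1% oxygen, and since these genes differ between the groups its size is no separate finding. Cluster 18, kept out of the class by the gap between scores, held 1.19% and 0.506% at 5%, 2.12% and 0.558% at 1% and 0% at 20% oxygen. The 1% minus 5% difference in the HSC-like share was -11.9 percentage points and was not separable from library spread: 2 against 2 libraries allow no two-sided exact permutation p below 0.333, and an edgeR test on cell counts gave an adjusted p of 0.458. The shares and their difference depended on the clustering. The difference was -2.45 points with resolution 0.5 and 15.5 points, the opposite direction, with called doublets kept and the cells clustered again, where the shares were 26.0% and 22.9% at 5% and 40.1% and 39.7% at 1% oxygen. At resolution 2.0 the second 1% library had a share of 28.2%.

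The 20% oxygen culture was spread over other clusters. Neutrophil-like cells made up 10.8% of it, against 0.509% and 1.42% at 5% and 0.112% and 0.353% at 1% oxygen, and mast or basophil-like cells 5.78%, against 0.127% and 0.203% at 5% and 0% and 0.0228% at 1% oxygen. The sizes of both classes at 20% oxygen depended on the clustering and the cells used. The mast or basophil-like share was 3.17% with 4000 variable genes, 14.3% at resolution 0.5, 21.4% with all genes allowed and 31.6% with the stricter cell filter, though at most 0.473% in any other culture. The neutrophil-like share lay between 8.62% and 17.5%, and with the stricter filter no cluster was so named. Unnamed clusters held 82.9% of its cells: cluster 4 (35.2%), led by the stress genes Atf5, Nupr1 and Trib3, cluster 8 (16.4%), led by histone genes, cluster 10 (13.8%), led by Cpa3 and Mpo, and cluster 13 (10.7%), led by Fcer1a and Gzmb. Each of these 4 clusters held at most 0.270% of any other culture, and since they came almost wholly from 1 library they may be that library and not a type. Its cells were also the deepest, at a median of 25278 UMIs.

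Within HSC-like cells the 1% against 5% contrast was tested again. Bnip3 rose by 1.55 ± 0.21 (adjusted p = 0.0178), Hist3h2ba by 1.52, Slc2a1 by 1.30, Il10ra by 1.27 and Egln3 by 1.25. Plac8 had the largest fall (-2.59 ± 0.11, adjusted p = 2.85e-15), from 83.4 and 75.4 CPM to 12.6 and 14.1 CPM, followed by Ung (-1.26), which removes uracil from DNA, Oas1a (-1.17), Phpt1 (-1.14) and Ifi44 (-1.11). Of 37 hypoxia response genes 24 rose and 0 fell (27 and 0 adjusted over the list alone), of 18 glycolysis genes 10 rose and 0 fell (11 and 1), of 24 cholesterol synthesis genes 18 rose and 0 fell (19 and 0), and of 23 interferon genes 14 fell and 0 rose (15 and 0). G2 and M phase genes had 41 rises and 0 falls among 51 (47 and 0 adjusted over the list alone), with Ccnb2 at 0.85 and Cdc20 at 0.87. S phase genes had 25 falls and 0 rises among 42 (32 and 1 adjusted over the list alone), with Pcna at -0.77 and Mcm4 at -0.67. Cluster 2, led by mitotic genes, was in this class, whereas cluster 5, led by S phase genes such as Uhrf1 and Mcm2, was unnamed and held 7.04% and 4.83% of cells at 5% and 16.0% and 14.9% at 1% oxygen. Each of these lists passed camera at the preset correlation. With an estimated correlation the adjusted p was 0.757 for G2 and M phase and 0.573 for the other 5 lists. The clusters summed here differed in share between the groups. Cluster 3 went from 28.9% and 30.3% of kept cells at 5% to 11.7% and 3.78% at 1% oxygen. The interferon-led cluster 9 went from 10.5% and 11.8% to 6.09% and 1.67%. Cluster 1 went from 10.5% and 6.68% to 23.8% and 24.2%, and cluster 2 from 14.2% and 14.9% to 15.1% and 17.5%. Equal-share values were made for whole libraries only, so changes in this fit may partly reflect this mix.

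Of 17 tested HSC-like markers 5 fell and 0 rose in these cells (9 and 0 adjusted over the list alone): Ctnnal1 (-1.04), Mllt3 (-0.60), Tcf15 (-1.09), Pdzk1ip1 (-0.48) and Esam (-0.68). The list's adjusted p was 0.00119 by camera at the preset correlation and 0.757 with an estimated correlation, and the cells had been put in the class by these same markers. In all 871 genes were higher and 812 lower by edgeR's quasi-likelihood test. That count of 1683 moved to 859 without the first 5% library, 389 without the second, 338 with the DESeq2 Wald test, 1068 with the stricter cell filter, 651 with doublets kept and 842 with cells thinned to 2000 UMIs. The stricter filter was applied to the same HSC-like cells, whereas with doublets kept the cells were clustered again. In that new class Ung was at 0.15 (adjusted p = 0.808).

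Marker genes of HSCs were also counted per cell at an equal depth of 2000 UMIs. Ly6a was found in 39.7% and 41.2% of cells at 5% oxygen, 34.3% and 35.8% at 1%, 2.63% at 20% and 2.15% in fresh marrow. Hlf, a transcription factor of HSCs, was found in 31.6% and 25.3% of cells at 5%, 30.4% and 22.3% at 1%, 8.04% at 20% and 15.9% in fresh marrow. Procr, which encodes the endothelial protein C receptor, was found in 3.21% and 3.17% of cells at 5%, 3.26% and 1.87% at 1%, 0.719% at 20% and 0.878% in fresh marrow, and the 1% minus 5% difference of -0.63 points was smaller than the gap between the 1% libraries. Unthinned, Procr was found in 22.6% and 24.1% at 5%, 18.1% and 5.23% at 1%, 8.34% at 20% and 3.33% in fresh marrow, a difference of -11.7 points that follows depth. In neutrophil-like cells, which should lack these genes, the shares at the same thinned depth were 0.486% for Ly6a, 0.648% for Hlf and 0 of 617 cells for Procr (exact upper limit 0.596%) at 20% oxygen, and 0.271%, 9.28% and 0.339% in fresh marrow. Their median depths before thinning were 23032 and 7771 UMIs. In the 87 neutrophil-like cells of the 5% and 1% cultures together (median depth 15150 UMIs) the shares were higher for Ly6a, at 11.5% (10 cells, interval 5.65% to 20.1%), and 2.30% for Hlf (2 cells) and 0% for Procr (upper limit 4.15%), so part of the Ly6a share of those cultures may be background. Part of the Hlf share in fresh marrow may be background too, at 9.28% of neutrophil-like cells against 15.9% of all cells. Thinning left out 15.9% of fresh cells and between 0.175% and 2.13% of cells in the cultures.

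**Figure D3:**
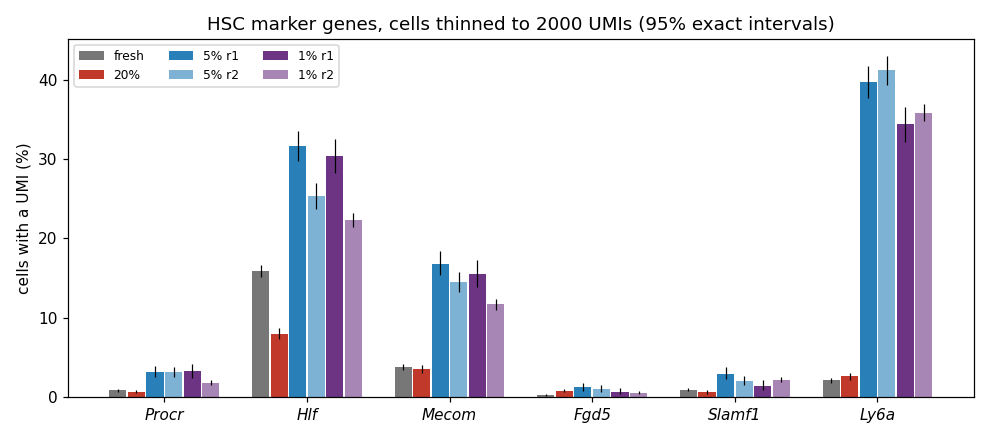
Percent of cells (vertical axis) with a UMI of 6 HSC marker genes after thinning every cell to 2000 UMIs, per library; each bar is 1 library and its line the 95% exact binomial interval. Ly6a was found in 34.3% to 41.2% of cells at 5% and 1% oxygen and in 2.63% at 20% oxygen.

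Fresh c-Kit+ marrow was set against the cultures by values alone, since it has 1 library and was not sorted for HSCs. Genes of mature and committed lineages were higher in fresh marrow: the globins Hba-a2 (350 CPM, against at most 0.0130 in any culture) and Hba-a1 (555 CPM), the neutrophil granule genes Camp (2995 CPM) and Ngp (3108 CPM), Cd177, Retnlg, Chil3, the erythroid genes Ermap and Car1, and the macrophage gene C1qa. Genes higher in the cultures were Enah (1.48 CPM in fresh marrow against a mean of 123 ± 38.3 SD, n = 5), S100a4, Socs2 (2.99 against 163 ± 63.0), a feedback inhibitor of cytokine signalling, Ly6a, Pim2, Ifitm1, Scin, Tnip3, Ccl5 and Ltb. The ratios rest on the mean of cultures that differ: in the 20% library Ly6a was at 13.6 CPM against 9.28 in fresh marrow, and Ccl5 at 21.3 against 12.3. All 11 B-lymphoid markers, 13 of 14 erythroid, 14 of 15 neutrophil and 8 of 8 macrophage markers were higher in fresh marrow than in every culture. Of 24 cholesterol synthesis genes 19 were lower in fresh marrow than in every culture, as were 9 of 10 STAT5 targets. HSC-like cells were 5.31% of kept fresh cells, neutrophil-like 24.6% and erythroid-like 10.1%; fresh cells were clustered apart from the cultures, at a median of 6320 UMIs.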

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

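The tests on the single 20% oxygen library and on cells poor in lineage markers, and both tests on high mitochondrial shares, were chosen or revised after the results were seen, as was the set of all other kept cells used beside HSC-like cells.

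The effect of 1% against 5% oxygen differed between HSC-like cells and all other kept cells for 975 genes in one direction and 1019 in the other of 13768 tested, by an interaction test in edgeR with Benjamini-Hochberg adjustment. The 5 genes with the smallest adjusted p include myeloid and antigen-presentation genes. For the lysosomal protease gene Ctss the difference was 2.44 (log2 fold 0.01 in HSC-like cells and -2.45 in the others), for Ahnak 1.78 (0.63 and -1.18), and for Cd74, the MHC class II invariant chain, 1.74 (0.70 and -1.08). For Fcer1g, an Fc receptor chain, it was 1.22 (0.18 and -1.05), and for the ferritin gene Ftl1 0.74 (0.18 and -0.56). The other cells are a mixture of clusters whose shares differ between libraries, and so are the HSC-like cells. In whole libraries the change of Ctss went from -1.77 to 0.13 with equal cluster shares. The counts may therefore reflect these shares and not a different response of the cells.

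Barcodes with over 10.0% mitochondrial UMIs, which the comparisons leave out, made up 35.4% and 32.9% of the 5% oxygen libraries and 30.2% and 11.7% of the 1% libraries, against 4.49% at 20% oxygen. The 2 libraries at 1% differed by 18.5 points at the same oxygen level, so oxygen alone is argued against as the whole cause, though this difference is part of the pattern and no separate test. In both 5% libraries and the first 1% library such barcodes had at most 0.222 of the median non-mitochondrial UMIs of the other barcodes, but the ratio was also low in the libraries with fewer of them (0.0643 at 20% and 0.268 in the second 1% library). A high mitochondrial share by itself favours few other UMIs, so damaged cells that lost cytoplasmic RNA and other sources cannot be told apart. Handling of each culture before loading stays open and untested.

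Integrated stress response genes were higher in the 20% oxygen library, with a median log2 fold of 1.09 against 5% oxygen. The part of granulocyte, mast and megakaryocyte cells in this was examined in cells poor in their markers. There were 1769 such cells at 20% oxygen, where these markers made up 3.76 of 10000 UMIs against 3.70 and 3.94 at 5%. In them the stress list median was 1.13, and 0.92 in the 690 left after removal of the 61.0% in the stress-led cluster 4. Mast or basophil (median 2.83), macrophage (1.70) and neutrophil (0.91) genes stayed higher in the 1769 cells. In the 690 cells these medians were 3.42, 2.80 and 0.62. The median of monocyte or dendritic genes was 0.48 in the 1769 cells and 1.78 in the 690. The selected cells were thus not free of these lineages. The stress medians therefore cannot decide whether cells of these lineages account for the higher stress genes. After thinning the stress list median was 1.05. Thinning keeps the expected gene proportions of each cell and counts were scaled per library, so this value cannot decide on the greater depth of the 20% library. With 1 library at 20%, the oxygen level and the culture or preparation of that library cannot be told apart, and a response to 20% oxygen stays a hypothesis.

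Interferon response genes were lower at 1% than at 5% oxygen, with a median log2 fold of -0.75. Fewer cells of the interferon-led cluster 9 are argued against as the whole cause by a median of -0.65 without that cluster. A single library that stands apart is argued against by medians of -0.79 to -0.62 with each library left out. After thinning the median was -0.68. Counts were summed and scaled per library, and thinning keeps the expected gene proportions of each cell. This value therefore cannot decide whether fewer UMIs per cell play a part. With equal shares of the 12 clusters used, which held 96.6% of the cells, the median was -0.23. A different mix of clusters may thus account for much of the fall. Interferon genes helped to form the clusters, however, and the mix could follow the response itself. In the single 20% library 22 of 23 of these genes were lower than at 5% (median -1.69). There the oxygen level cannot be told apart from the cell types or from that library, so no order with oxygen can be read from it. What lowered these genes at 1% stays open.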

How the results depend on the processing

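The removal of the highest doublet scores and of clusters was chosen after the data had been seen. Of the values of single genes, 1446 kept their direction and side of the threshold, 35 lost the call, 3 gained it and 1 turned: Ung in HSC-like cells was at 0.15 with called doublets kept, where the cells were clustered again. Besides calls lost without a library, at 1% against 5% oxygen the lost calls (adjusted p) were Bnip3 (0.136) and Ctnnal1 (0.198) with thinned cells, Ctss (0.0856) and Ccl6 (0.0599) with all barcodes, H2-Aa (0.155), Pdzk1ip1 (0.0548) and Esam (0.0964) with the stricter filter, Esam (0.0711) by DESeq2 and Lyz2 (0.0560) with the highest doublet scores removed. Without the interferon-led cluster they were Ctss (0.0535), Pdzk1ip1 (0.146) and Esam (0.142), and without the clusters scored as granulocyte, mast or megakaryocyte Ccl6 (0.0867). At 20% oxygen they were Ms4a2 against 5% with the stricter filter (0.0652), and Trpc6 without those clusters (0.0652 against 5%, and against 1% at a log2 fold of 0.93). Tcf15 gained its call at 1% against 5% without a filter on low counts (0.0234), with the stricter cell filter (0.0408) and without the first 1% library (0.0118). For 1% against 5% oxygen the call count was 1546 without a filter on low counts, 553 with the stricter cell filter, 580 with thinned cells and between 573 and 1258 with a library left out. Thinning gave 2928 calls at 20% against 5% and 3732 at 20% against 1%, where fewer UMIs were left to count. In HSC-like cells there were 338 calls by DESeq2, 1068 with the stricter filter, 651 with doublets kept, 842 with thinned cells and 389 to 2136 with a library left out. Apart from thinning the cause was not tested. The mean log2 fold of the hypoxia list was 0.72, and 0.60 to 0.82 with a library left out. Its camera call ended with an estimated correlation (adjusted p = 0.451, against 0.0403 by fry). With 2 residual degrees of freedom hardly any list could pass that form of camera. The HSC-like share difference was -2.45 points at resolution 0.5, -6.61 with all genes allowed, 15.5 with doublets kept, -29.8 with the stricter filter and a new clustering, -3.52 with the highest doublet scores removed and -16.7 to -7.10 with a library left out. The Procr difference was -11.7 unthinned. Of the 20 genes named for fresh marrow, 8 were shared with a CPM floor of 20 and 6 with a floor of 500.

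The replicate numbers share no stated origin, and same-numbered libraries had a correlation of deviations of 0.0691 across genes. With the replicate block the count at 1% against 5% oxygen was 817, in HSC-like cells 2306, and the hypoxia list mean was 0.71; the block changed no call of a named gene. The stricter HSC-like fit used the HSC-like cells of the original clustering that passed the filter, 0 of them in the 20% library, which it lacks; the stricter share came from the new clustering, with 2 such cells at 20%. The test against the largest other named class was not run, since no such class had 50 cells in every culture. Among the cultures, depth limits the second 1% library most, at a median of 6622 UMIs per kept cell.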

Other observations

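No test in this part was chosen after its result was seen, and the genes named are members of fixed lists.

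The values of some of the lists not described above at 20% against 5% oxygen follow, beside 2600 rises and 2455 falls among all 15222 genes tested. Of 18 immediate early genes 15 were tested, and against 5% oxygen 6 fell and 1 rose: Jund (-0.93), Klf6 (-0.50) and Egr2 (-2.14) fell and Junb rose (0.48), with an adjusted p = 0.566 with an estimated correlation. Of 8 tested T or NK genes 5 fell, among them Il2rb (-2.38) and Cd3g (-5.85), and Nkg7 rose (0.77). The eosinophil gene Prg3 rose (4.76) while Il5ra was at 0.53 and did not pass (adjusted p = 0.422). Nuclear oxidative phosphorylation genes had 19 rises and 5 falls among 75, and mitochondrially encoded genes 4 rises and 1 fall among 13. The filter on mitochondrial UMIs acts on the counts of the latter and removed unequal shares of barcodes between libraries. The macrophage list had 3 rises and 0 falls and the unfolded protein response list 4 rises and 3 falls, the latter with a median of -0.13 and a mean of 0.06. At the preset correlation the adjusted p was 0.928 for the unfolded protein response, 0.166 for mitochondrially encoded genes, 0.0916 for nuclear oxidative phosphorylation and 0.0932 for immediate early genes, so these 4 lists did not pass. The eosinophil, T or NK, macrophage and multipotent or lymphoid-primed progenitor lists did pass camera at that setting. With an estimated correlation no list of this contrast had an adjusted p below 0.344.

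Fresh marrow differed from the cultures in proliferation and early response genes as well. Of 42 S phase genes 39 and of 51 G2 and M phase genes 28 were higher in fresh marrow than in every culture, as were 14 of 18 immediate early genes (median log2 ratio 2.19). Of 18 HSC-like markers 9 were lower in fresh marrow than in every culture and 5 higher, and of 39 hypoxia response genes 14 were lower and 4 higher. These are values of 1 library from another population of cells, without a test.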
